A study of Mus musculus with 4 samples.

How the data were processed

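The series profiled messenger RNA of renal primary tubular epithelial cells, isolated from the kidney cortex of mice of the C57BL/6 strain at 8 weeks, by RNA sequencing of 4 libraries. Per the labels' protocols, total RNA was extracted with Trizol, treated with DNase, selected on poly(A) tails with magnetic beads and made into libraries with a directional kit, which keeps the strand of each RNA, and was sequenced as read pairs of 150 bases. The submitters' processing notes name cutadapt 1.9.1, Trimmomatic 0.35, FastQC, HISAT2, StringTie and MACS2 2.1.1 and the mouse genome build GRCm38 (mm10), without saying what each tool was used for. The program that counted reads per gene, whether it used strand and how it treated reads matching several genes are not given in the sources used here.

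The authors deposited a table of 18383 genes with raw read counts per gene for each of the 4 libraries, per the file headers, and the lowest sum of a gene over the 4 libraries was 10. The same table holds the authors' mean signal per group, which equals the group mean of the counts after division by median-ratio size factors to within 0.00021. It also holds the authors' fold change as a ratio of these means, and its log2 value, per the file headers, which is set to 20 or -20 for 476 genes with a group at 0. The authors' p-value and adjusted p-value per gene come from a test that is not named in the sources used here. A last set of columns in the authors' deposited table gives the mean raw counts per group and their ratio, with no correction for depth. A second table repeats part of these ratios and was not used here. Every column with values per library matched the description label of 1 sample, and the number of value columns left unmapped was 0.

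Libraries were grouped by the genotype in their labels, KM with 2 libraries and KMS with 2. The labels do not say that replicates came from separate animals, although the titles carry separate numbers. P-values measure the spread between these libraries. Counts were tested with edgeR 4.0.16 in R 4.3.3, using TMM factors, the quasi-likelihood F test and the genotype as the only term. The filterByExpr filter (minimum count 10, minimum total 15) left 15002 genes. A gene was called when its adjusted p (Benjamini-Hochberg, edgeR) was under 0.05, and positive log2 fold changes mean higher in KMS. The standard error (SE) of a log2 fold change was taken from the F statistic. Expression is given as CPM, the count divided by the TMM-adjusted total and scaled to 1e+06, and ratios within a pair of libraries were taken after adding 0.5 CPM. Total counts ranged from 8886496 to 18639040 per library, so 3 counts, the floor used where a group had none, correspond to a mean of 0.337 CPM in KMS. Floors and Poisson intervals cover counting error only, as the reads carry no molecular identifiers in the sources used here.

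Gene lists for 22 biological themes and 3 checks on the libraries were written from textbook knowledge before the data were examined. They were tested with camera (limma 3.58.1, preset correlation 0.01, two-sided, Benjamini-Hochberg over the 25 lists). Camera with an estimated correlation and fry were alternatives. Of the listed genes, 9 had no row. The rule for the genes named in the text was also fixed then. It took Setd2 and Myc first. It then took the 10 largest changes each way among called genes with a regular symbol, a mean of at least 1 CPM and groups that do not overlap. From each list it took up to 4 members of smallest p if it held a call, or up to 2 otherwise as values with no call. Because only 3 genes met the second part, the same rule was also applied to a fit with a term for sex, which was added after the data were seen. Named genes outside the rule are marked as such, and 1 gene that the rule takes is not reported here.

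Positions and gene types come from the RefSeq annotation of GRCm38.p6, the same build, in which 16129 of the symbols matched, and overlaps of genes and GC content from GENCODE M21. Alternatives fixed before the data were examined were DESeq2 size factors, upper-quartile factors and library totals in the edgeR fit, the DESeq2 1.42.0 Wald test, limma-voom, other filters and thresholds, a replicate block, each library left out, and the removal of mitochondrial, haemoglobin and sex-linked genes. Robust estimation, the removal of genes of RNAs without poly(A) tails, and DESeq2 with the block were added later. The fits were tested on counts simulated for the comparison of KMS with KM over 15002 genes, with 100 genes changed 2-fold and 100 changed 4-fold. The edgeR fit with genotype alone recovered 8 and 64 of these and called 11 unchanged genes. With the replicate block it recovered 26 and 78 and called 52 unchanged genes, while DESeq2 recovered 28 and 78 with 32 unchanged. limma-voom recovered 3 and 58 with 8 unchanged.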

Results

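RNA was measured in renal tubular epithelial cells of mice of 2 genotypes. Per the labels, KM mice carried floxed MYC alleles and the KspCre transgene, and KMS mice carried floxed SETD2 alleles in addition. The promoter of kidney-specific cadherin drives Cre recombinase in KspCre mice. SETD2 is the methyltransferase that trimethylates histone H3 at lysine 36. The series title describes the comparison as MYC cells with and without SETD2, and the question was which transcripts differ between them. There were 2 libraries per genotype, with total counts of 18639040 and 14955148 in KM and 9780050 and 8886496 in KMS, so KM libraries were on average 1.80 times as deep. The logarithmic CPM of the replicates correlated across genes at 0.955 in KM and 0.963 in KMS, and between genotypes at 0.884 to 0.952 (genes are not independent replicates). The replicates of each genotype differed by far more than sampling noise, with a chi-square per degree of freedom of 53.6 in KM and 40.1 in KMS.

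Setd2 (chromosome 9, 110532500 to 110618633, GRCm38) had 1006 and 949 counts in KM and 564 and 405 in KMS. This corresponded to 56.1 ± 2.63 CPM in KM and 53.7 ± 6.46 CPM in KMS (SD, n = 2 each), and the groups overlapped. The log2 fold change was -0.06 ± 0.17 (SE, edgeR adjusted p = 0.843). The labels do not name the floxed exons, and a count over the whole gene may include reads outside the deleted part, so this value does not check the genotype labels. Myc (chromosome 15, 61985341 to 61990361), the transcription factor gene whose allele is shared by both genotypes, had 6.12 ± 1.19 CPM in KM and 4.14 ± 2.77 CPM in KMS (SD, n = 2). Its log2 fold change of -0.55 ± 0.51 (SE) did not pass the test (edgeR adjusted p = 0.525). The genotype label gives floxed MYC alleles and the series title MYC+, and whether this count measures the engineered allele is not given in the sources used here.

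In KMS, transcripts of the nephron tubule and of mitochondrial energy metabolism were higher as groups. Those of tubular injury, cell division, leukocytes and extracellular matrix were lower as groups. These calls rest on camera's preset correlation, as 0 of 25 lists passed with an estimated correlation (lowest adjusted p = 0.581, limma) and 0 with fry (lowest adjusted p = 0.304, limma). Gene by gene, 5 of 15002 genes passed the test. The ribosomal protein gene Rpl29 (chromosome 9, 106428889 to 106431568) fell from 69.0 ± 4.01 to 0.777 ± 0.07 CPM (SD, n = 2; log2 fold change -6.45 ± 0.25 SE, edgeR adjusted p = 0.0027). ND6 (mitochondrial genome, 13552 to 14070), a subunit of respiratory complex I, fell from 869 ± 45.1 to 59.9 ± 3.15 CPM (log2 fold change -3.86 ± 0.25 SE, edgeR adjusted p = 0.022). Kcnq1ot1 (chromosome 7, 143213111 to 143296547), an imprinted long non-coding RNA transcribed antisense to Kcnq1, fell from 92.6 ± 38.8 to 4.04 ± 0.46 CPM (log2 fold change -4.52 ± 0.37 SE, edgeR adjusted p = 0.049). Outside the rule for named genes and chosen after their values were seen are the other 2 calls. LOC101056102, described in the file as a sequence like a retroviral envelope protein, fell from 53.4 ± 5.55 to 5.83 ± 1.55 CPM (log2 fold change -3.19 ± 0.26 SE, edgeR adjusted p = 0.049). Gm6197 (chromosome 3, 25731226 to 25732613), a pseudogene, had 3 counts in KM and 269 in KMS, a ratio of 175 for a 95% Poisson interval of 59.1 to 852 (edgeR adjusted p = 0.022). All 5 are uncertain. Rpl29, Gm6197 and LOC101056102 can share reads with near-identical sequences elsewhere. Reads of ND6 and Kcnq1ot1 cannot be told from those of the opposite strand unless counting used strand. Whether ND6 also follows the lower level of RNAs without poly(A) tails in KMS, described below, was not tested.

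**Figure D1:**
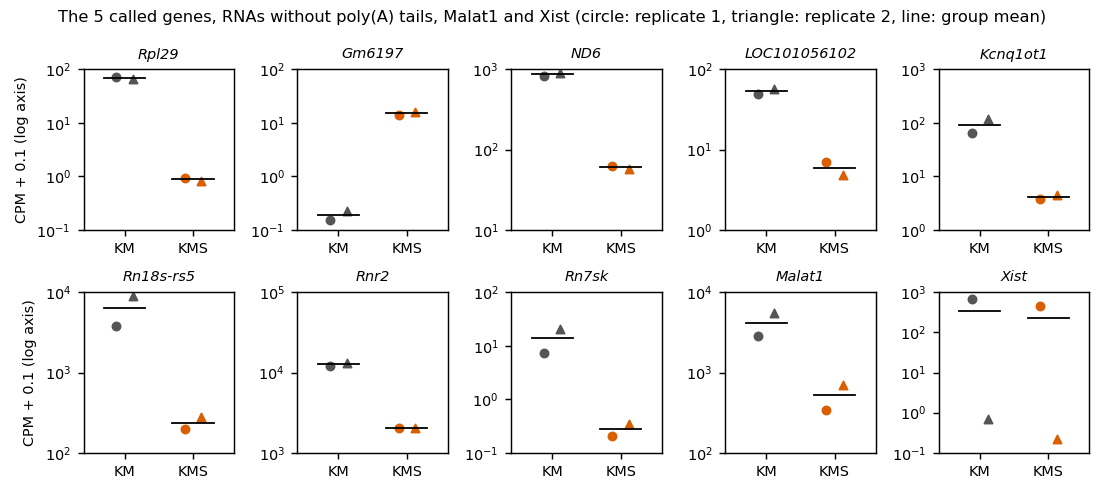
Each panel plots 1 gene as CPM plus 0.1 on a log axis for the KM and KMS libraries, with circles for replicate 1, triangles for replicate 2 and lines for group means. The upper row holds the 5 called genes, Rpl29 at 69.0 CPM in KM and 0.777 in KMS among them, and the lower row holds RNAs without poly(A) tails, Malat1, and Xist, which separates the replicates in both groups.

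The number of calls depended on the model. An unadjusted p under 0.05 was reached by 3944 genes (1828 higher and 2116 lower) where 750 would be reached by chance. Groups did not overlap for 60.4% of tested genes, against 33.3% by chance. Genes of the same libraries are not independent, so these excesses do not by themselves measure an effect of genotype. For 2 against 2 libraries, a permutation test cannot give a two-sided p under 0.333. No gene was called without KMS replicate 1 or without KMS replicate 2, 169 were called without KM replicate 2, and 1786 without KM replicate 1. Replicate 1 of each genotype was rich in Xist, the RNA that silences an X chromosome in females, with 12967 counts in KM and 4363 in KMS, and had 1 and 0 counts of Y-linked genes. Replicate 2 of each had 10 and 1 counts of Xist and 3410 and 1471 of Y-linked genes. With a term for sex added to the edgeR model after this was seen, 815 genes passed (290 higher and 525 lower in KMS), among them all 5. On simulated counts for this comparison that model called 52 unchanged genes, beside 26 and 78 of 100 genes changed 2-fold and 4-fold. Part of the 815 calls are therefore expected to be false. Without sex-linked genes, the deviations of libraries of equal sex correlated at only 0.0646 between the genotypes. By the authors' deposited table, 409 genes had an adjusted p under 0.05 (246 higher and 163 lower), including all 5 called here and 315 of the 815.

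Markers of the proximal tubule, the segment that reabsorbs most filtered solutes, were higher in KMS as a group, with a median log2 fold change of 1.17 over 26 genes and 25 of them positive (limma camera adjusted p = 7.7e-09, adjusted p = 0.581 with an estimated correlation). None passed over all genes, and 13 rose when adjusted over the list alone. The water channel gene Aqp1 had 208 ± 59.6 CPM in KM and 518 ± 23.1 CPM in KMS (SD, n = 2; log2 fold change 1.32 ± 0.28 SE, edgeR adjusted p = 0.084), and Miox, the oxygenase that breaks down inositol, 849 ± 235 and 2272 ± 36.3 CPM. The term for sex gave 5 members that rose. They were Aqp1, the glucose transporter gene Slc5a2 (385 ± 167 to 989 ± 248 CPM), the glucose-6-phosphatase gene G6pc, the organic anion transporter gene Slc22a6 and, outside the rule, Slc5a12. The 16 genes of the loop of Henle and distal tubule had a median of 1.03, with 14 positive (limma camera adjusted p = 3.6e-04, adjusted p = 0.581 with an estimated correlation), and 0 passed even when adjusted over the list alone. In the model with sex 4 rose, Egf at 308 ± 318 and 1280 ± 755 CPM, Pvalb at 3.29 ± 3.96 and 34.8 ± 5.37 CPM, the potassium channel gene Kcnj1 and Ppp1r1a. Podocyte markers, from the glomerulus, also had a higher median of 0.59 with 9 of 9 positive and 0 called (limma camera adjusted p = 0.038, adjusted p = 0.742 with an estimated correlation), for example Clic5 at 172 ± 47.9 and 273 ± 19.4 CPM and Cdkn1c at 99.8 ± 40.1 and 158 ± 16.3 CPM.

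Genes of oxidative phosphorylation moved together. All 22 were higher in KMS by value, with a median log2 fold change of 0.75 (limma camera adjusted p = 2.1e-08, adjusted p = 0.581 with an estimated correlation), and 13 rose when adjusted over the list alone, while 0 passed over all genes or with the term for sex. Cyc1, a subunit of complex III, had 190 ± 28.4 CPM in KM and 370 ± 6.61 CPM in KMS, and Ndufv1 of complex I 157 ± 24.7 and 314 ± 46.1 CPM (SD, n = 2). The 23 genes of fatty acid oxidation were likewise all positive, with a median of 0.76 (limma camera adjusted p = 8.5e-07, adjusted p = 0.581 with an estimated correlation), and 7 rose when adjusted over the list alone. Acaa1b, a peroxisomal thiolase gene, had 124 ± 22.4 and 266 ± 25.1 CPM, and Ech1 197 ± 37.8 and 411 ± 49.9 CPM. In the model with sex, 1 member of the list passed, the mitochondrial thiolase gene Acaa2, which rose from 190 ± 46.4 to 457 ± 113 CPM. The 29 genes of hypoxia and glycolysis had a median of 0.22 (limma camera adjusted p = 0.039, adjusted p = 0.581 with an estimated correlation), with 3 that rose and 2 that fell when adjusted over the list alone. The group call was lost with the term for sex (limma camera adjusted p = 0.062). In that model 2 members passed. Angptl4, an inhibitor of lipoprotein lipase that also responds to fasting, rose from 10.5 ± 2.23 to 60.2 ± 2.88 CPM. The hexokinase gene Hk2 fell, with 3.7 and 31.0 CPM in the KM libraries. The medians in the female and male pairs were 0.99 and 1.41 for the proximal tubule, 0.586 and 1.498 for the loop of Henle and distal tubule, 0.30 and 0.96 for podocytes, 0.52 and 0.97 for oxidative phosphorylation, 0.60 and 0.90 for fatty acid oxidation and 0.27 and 0.10 for hypoxia and glycolysis.

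**Figure D2:**
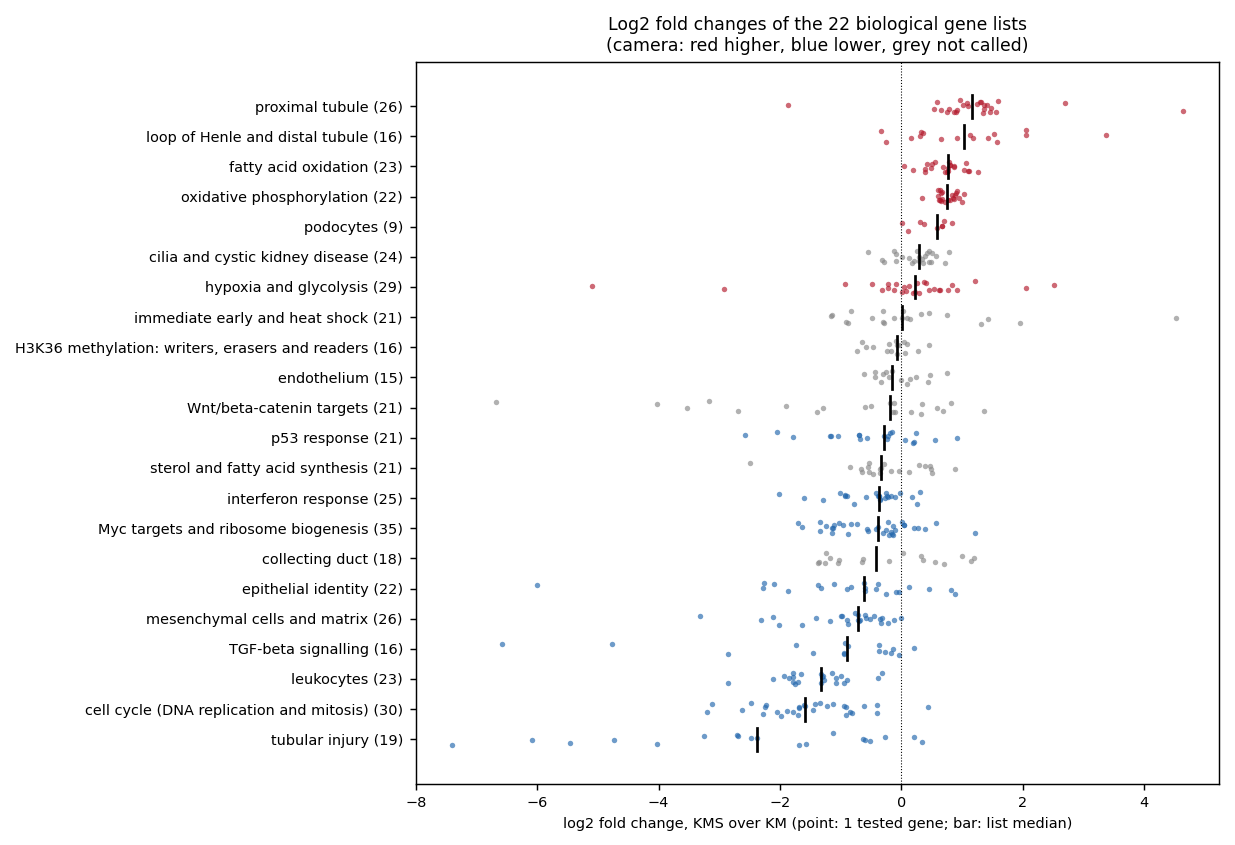
The horizontal axis is the log2 fold change of KMS over KM from edgeR, each point is a tested gene, each bar the median of its list, and the number tested follows the name of the list. Colours show the camera calls, red for higher and blue for lower, from a median of 1.17 for the proximal tubule to -2.37 for tubular injury, and Mmp7, with no count in KMS, is drawn at its bound.

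Genes induced in injured tubules had the lowest median in KMS among the 25 lists written before the data were examined. It was -2.37 over 19 genes with 17 negative (limma camera adjusted p = 9.9e-09, adjusted p = 0.581 with an estimated correlation). Of these, 12 fell when adjusted over the list alone and 7 with the term for sex. Vcam1, an adhesion molecule of tubules that fail to repair, fell with that term from 61.2 ± 21.3 to 9.33 ± 3.76 CPM (SD, n = 2; log2 fold change -2.69 ± 0.37 SE, edgeR adjusted p = 0.012), and the transcription factor gene Sox9 from 14.6 ± 8.94 to 0.881 ± 0.22 CPM. Havcr1, which encodes the kidney injury molecule KIM-1, and the complement gene C3 also fell with that term, but rested largely on KM replicate 2. KM replicates 1 and 2 had 9.0 and 108.6 CPM of Havcr1 and 158.8 and 1822.5 CPM of C3. Cell cycle genes had a median of -1.59, with 29 of 30 negative (limma camera adjusted p = 1.25e-08, adjusted p = 0.581 with an estimated correlation), and 7 fell when adjusted over the list alone. The term for sex gave 3 that fell, the proliferation marker Mki67 (28.6 ± 19.4 to 3.08 ± 0.76 CPM), the centromere protein gene Cenpe and the cyclin gene Ccna2. Leukocyte markers were negative for 23 of 23 genes with a median of -1.32 (limma camera adjusted p = 9.9e-09, adjusted p = 0.581 with an estimated correlation), and 15 fell when adjusted over the list alone. The macrophage marker Cd68 fell with the term for sex from 24.6 ± 4.55 to 5.62 ± 3.31 CPM, and Ptprc, which encodes the pan-leukocyte antigen CD45, had 58.2 ± 16.3 and 24.1 ± 7.68 CPM.

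Genes of mesenchymal cells and matrix had a median log2 fold change of -0.72 with 26 of 26 negative (limma camera adjusted p = 6.9e-06, adjusted p = 0.581 with an estimated correlation), and 6 fell when adjusted over the list alone. In the model with sex 5 fell, the collagen genes Col1a1 (21.9 ± 14.9 to 2.18 ± 0.01 CPM, SD, n = 2), Col3a1 (32.1 ± 15.6 to 7.42 ± 1.87 CPM), Col5a2 and, outside the rule, Col1a2, and the crosslinking enzyme gene Lox. For Col5a2 the groups overlapped, with 133.3 and 65.2 CPM in KM and 70.8 and 28.6 CPM in KMS (edgeR adjusted p = 0.259 without the term for sex). TGF-beta signalling genes had a median of -0.90 with 15 of 16 negative (limma camera adjusted p = 2.5e-04, adjusted p = 0.581 with an estimated correlation), 6 of which fell when adjusted over the list alone. Skil, a repressor of SMAD proteins, fell with the term for sex from 47.8 ± 1.89 to 24.8 ± 0.92 CPM, as did Ltbp2 and Tgfb2, the latter with 19.2 and 515.3 CPM in the KM libraries. The medians in the female and male pairs were -0.66 and -2.94 for injury, -0.58 and -1.91 for the cell cycle, -0.61 and -1.92 for leukocytes, -0.43 and -0.90 for matrix and -0.35 and -1.14 for TGF-beta.

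Of 35 Myc targets and genes of ribosome biogenesis, 27 were negative with a median of -0.39 (limma camera adjusted p = 3.5e-04, adjusted p = 0.581 with an estimated correlation), and 13 fell and 1 rose when adjusted over the list alone. With the term for sex 6 fell, including the nucleolin gene Ncl (145 ± 17.1 to 66.2 ± 4.04 CPM, SD, n = 2), Cad, which starts pyrimidine synthesis (37.9 ± 12.7 to 12.1 ± 2.57 CPM), Gnl3 and Ppan. Genes of epithelial identity had a median of -0.61 with 18 of 22 negative (limma camera adjusted p = 5.1e-04, adjusted p = 0.581 with an estimated correlation), and 8 fell when adjusted over the list alone. The model with sex gave 3 that fell, the tight junction gene Cldn4, the protease gene St14 (50.6 ± 24.4 to 13.9 ± 2.37 CPM) and the keratin gene Krt19, which had 10.6 and 90.7 CPM in the KM libraries and 0.620 and 0.971 CPM in the KMS libraries. Markers of urothelium and basal keratins, a list added after the data were seen, fell with this group, with a median of -5.82. Their summed CPM was 20.6 and 163 in KM and 1.76 and 2.79 in KMS. The genes of this list were chosen partly for their values, so its test is not independent evidence (limma camera adjusted p = 1.4e-09 over 4 added lists, p = 0.124 with an estimated correlation). The p53 response had a median of -0.29 (limma camera adjusted p = 0.023, adjusted p = 0.581 with an estimated correlation), and with the term for sex 2 of 21 members fell, Eda2r (7.56 ± 0.06 to 1.25 ± 0.57 CPM) and the pro-apoptotic gene Bbc3 (8.02 ± 0.83 to 2.33 ± 0.66 CPM). Interferon response genes had a median of -0.37 (limma camera adjusted p = 0.038, adjusted p = 0.830 with an estimated correlation) and 0 of 25 called in either model, with Rsad2 at 37.2 ± 2.88 and 21.8 ± 3.18 CPM and Gbp3 at 25.3 ± 7.37 and 12.6 ± 1.97 CPM. The interferon call was also lost with the term for sex (adjusted p = 0.059, limma camera), and its median was 0.16 in the female pair and -0.90 in the male pair, so the lower value came from the male pair alone. The other medians in the female and male pairs were -0.29 and -0.41 for Myc targets, -0.36 and -0.98 for epithelial identity and -0.29 and -0.60 for p53.

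**Figure D3:**
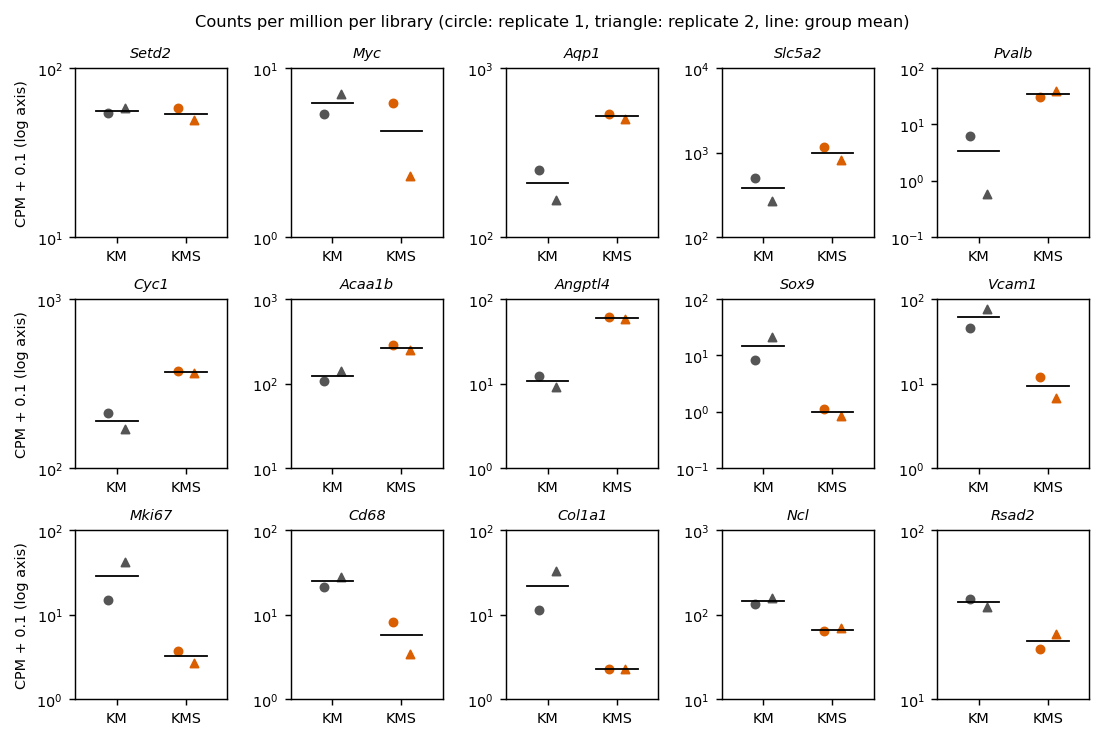
Each panel plots 1 gene as CPM plus 0.1 on a log axis for the KM and KMS libraries, with circles for replicate 1, triangles for replicate 2 and lines for group means. Setd2 and Myc overlap between the groups, while Aqp1 and Cyc1 lie higher and Sox9, Mki67 and Cd68 lower in both KMS libraries.

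The other 10 lists, of which 3 are checks on the libraries, were not called. Wnt/beta-catenin targets had a median log2 fold change of -0.19 (limma camera adjusted p = 0.053, and 0.0089 with the term for sex, where the call was lost with an estimated correlation at adjusted p = 0.672). In it 3 of 21 fell when adjusted over the list alone, and also with the term for sex. These were Sox9 and Cd44, which the injury list also holds, and the metalloproteinase gene Mmp7. In the collecting duct list of 18 genes (median -0.42, limma camera adjusted p = 0.222) 4 fell when adjusted over the list alone. These 4, the intercalated cell genes Atp6v1g3 (91.1 ± 10.3 to 35.6 ± 7.89 CPM, SD, n = 2), Atp6v0d2 and Aqp6 and the transcription factor gene Gata3, also fell with the term for sex, while Aqp2 and Scnn1g, outside the rule, rose. The H3K36 methylation list (median -0.08, limma camera adjusted p = 0.514) held 0 calls in 16 genes, with Psip1 at 41.3 ± 4.61 and 27.6 ± 1.22 CPM and Smyd2 at 30.6 ± 0.06 and 22.2 ± 3.48 CPM. Endothelial markers had a median of -0.15 (limma camera adjusted p = 0.997), with Cldn5 at 17.2 ± 7.03 and 29.1 ± 1.80 CPM and Egfl7 at 40.8 ± 5.56 and 55.3 ± 12.5 CPM. Genes of cilia and cystic disease had a median of 0.28 (limma camera adjusted p = 0.090), with Bbs4 at 11.7 ± 3.27 and 20.2 ± 3.08 CPM and Pkd1 at 39.1 ± 0.28 and 52.3 ± 6.46 CPM. Sterol and fatty acid synthesis had a median of -0.33 (limma camera adjusted p = 0.514), the desaturase gene Scd1 fell with the term for sex from 129 ± 85.4 to 22.9 ± 2.06 CPM, and Nsdhl had 56.8 ± 2.86 and 105 ± 15.2 CPM. Immediate early genes had a median of 0.01 (limma camera adjusted p = 0.397). Under the term for sex Fosb (0.781 ± 0.19 to 18.1 ± 13.1 CPM) and the phosphatase gene Dusp1 (39.2 ± 6.45 to 105 ± 26.9 CPM) rose and Klf4 fell.

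With the term for sex, the rule for the largest changes took 10 genes each way. Higher were Gbp2b and Ifi44l, both known as interferon-inducible, with 2 counts each in KM and 223 and 121 in KMS. Their ratios were 217 (95% Poisson interval 59.4 to 1804) and 118 (31.9 to 984). Fosb, R3hdml, Pvalb, Cacna2d2, the lipid kinase gene Pik3c2g (4.80 ± 0.91 to 57.9 ± 27.8 CPM, SD, n = 2), Xlr3b, Tspan1 (5.07 ± 3.20 to 34.0 ± 3.25 CPM) and the carbonic anhydrase gene Car3 followed. The 10 largest decreases were in genes with no count in either KMS library. They were Cuzd1, Mmp7, Kcne2, Tmprss11e, Sftpd, Krt15, Fxyd3, Krt5, Upk3bl and Rmrp. Cuzd1 was at least 172-fold lower, Mmp7 at least 102-fold lower and Rmrp at least 34.5-fold lower, against a floor of 3 counts per library. KM replicate 2 decided these values, with 3.14 (Rmrp) to 39.9 (Kcne2) times the CPM of KM replicate 1, for example 7.2 and 108.8 CPM of Cuzd1. Where both KMS libraries are at 0, the term for sex takes up the whole difference between the KM replicates. Passing in that model therefore does not weigh this difference. The SE of the Cuzd1 log2 fold change was 2.76 without the term and 0.65 with it. None of the genes in these groups of 10 passed in edgeR without the term for sex, where Gbp2b came nearest (adjusted p = 0.058).

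RNAs that lack a poly(A) tail also differed between the libraries. Of the total counts, 18S ribosomal RNA (Rn18s-rs5) took 0.377% and 0.983% in KM and 0.0194% and 0.0257% in KMS, and mitochondrial ribosomal RNA 1.81% and 2.19% in KM and 0.291% and 0.278% in KMS. Over 38 genes of such RNAs, chosen as a class after the data were seen, the median log2 fold change was -1.73, 37 were negative and 30 were lower in both KMS libraries than in both KM libraries. None passed over all genes in edgeR (lowest adjusted p = 0.066), and the nuclear RNA Malat1 had 4162 ± 1884 CPM in KM and 521 ± 259 CPM in KMS (SD, n = 2). Messenger RNAs of the mitochondrial genome made up 31.8% and 26.4% of counts in KM and 22.8% and 24.0% in KMS. As a list they were not called (13 genes, median -0.14, limma camera adjusted p = 0.258). ND6 was lower, with a log2 fold change of -3.86, where the next lowest of the list, ND5, had -0.76. The mitochondrial ribosomal RNAs Rnr1 and Rnr2, which are in the class without poly(A) tails, had -2.785 and -2.64. ND6 was not placed in that class, and whether its fall has the same source was not tested. ND3 had 25.4 ± 5.49 and 59.7 ± 2.86 CPM and rose in the model with sex, while ATP8 had 109 ± 23.4 and 71.2 ± 0.10 CPM and COX3 201 ± 28.9 and 315 ± 26.0 CPM. Erythrocyte genes (median -1.20, limma camera adjusted p = 0.514) followed KM replicate 1, with 12248 counts of Hbb-bs there and 715, 1313 and 1132 in KM replicate 2 and the KMS libraries. Sex-linked genes were not called as a list (median -0.36, limma camera adjusted p = 0.997). Every group of genes above was compared between libraries that also differed in ribosomal RNA, of which both KM libraries held more than both KMS libraries.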

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

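The patterns below were found in the results, so no test of them was fixed before the data were examined. The tests of carry-over, of other cell types and of Rpl29 were chosen only after their results were seen. Predictions for the others were written before those tests were run. Some values went opposite ways in the female pair (replicate 1) and the male pair (replicate 2), with 1 library per genotype in each pair, so the difference between the pairs was not tested. The log2 ratio of KMS to KM of Alas2, the erythroid enzyme of haem synthesis, was -2.64 in the female pair and 1.14 in the male pair. The median of the erythrocyte genes was -2.02 in the female pair and 1.68 in the male pair. The median of the immediate early and heat shock genes was 0.71 in the female pair and -0.70 in the male pair. In the same order the medians were 0.16 and -0.90 for the interferon response, which was called as lower, 0.16 and -0.53 for sterol and fatty acid synthesis, -0.41 and 0.26 for mitochondrial transcripts and 0.05 and -0.12 for the endothelium.

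The first pattern is the lower level of RNAs without poly(A) tails in KMS, with a median log2 fold change of -1.73 over 38 genes. After the KM counts were thinned to the mean KMS total, the median was -1.84. Thinning leaves the expected ratios of CPM unchanged. The result therefore speaks only to the gene filter and the handling of low counts, which did not account for the pattern. Counting without strand in KM predicts lower values in KMS for genes nested in a coding gene on the opposite strand. These lay 0.188 above separate non-coding genes (95% interval 0.0175 to 0.371, 261 and 175 genes). The nested set held coding as well as non-coding genes, and the separate set non-coding genes only. As the sets differ in gene type, this comparison cannot exclude counting without strand. Carry-over of unselected RNA that varied between libraries stays open as a candidate explanation, as 29 of 30 snoRNA genes were higher in KM replicate 2 than in KM replicate 1, by a median of 1.05 on the log2 scale within a genotype. An effect of SETD2 on these RNAs stays open too, since preparation of the libraries and genotype cannot be separated here.

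The second pattern is the higher level of tubule markers with lower leukocyte, injury and cell cycle genes in KMS. More cells of every other type in KM predicts that their markers fall alike. Instead, the endothelial median lay 1.18 above the leukocyte median, and podocyte markers were higher in KMS. The permutation test of that gap (two-sided, p = 0.0023) treated genes as independent, so it does not measure the spread between libraries. Genes within these lists were correlated, at an estimated 0.772 for endothelium and 0.600 for leukocytes. An uneven difference in cell types was not tested and stays open. Matrix genes (median -0.72) and urothelium and basal keratins (median -5.82) were also lower in KMS. GC content and transcript length do not account for it, since after their removal the smallest of the 4 list medians, taken in its direction, was 1.13. The library difference behind the RNAs without poly(A) tails may contribute, as KM replicate 2, richer in them than KM replicate 1, lay farther from KMS in all 4 lists, although this rests on 2 libraries that also differ in sex. A difference in injury or inflammation between the genotypes, or between the animals, stays open and was not tested.

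The third pattern is the near absence of Rpl29 counts in KMS (1333 and 1084 in KM, 8 and 6 in KMS). Reads assigned to copies of the gene, or to none of them, are a candidate explanation, because the most abundant of its 7 annotated copies, Gm13841, had a log2 fold change of 0.52 (edgeR adjusted p = 0.145, both KMS libraries above both KM libraries) where 76 other ribosomal protein genes had a median of -0.44. The gain of this copy, from 64.3 and 54.9 CPM in KM to 80.3 and 90.3 CPM in KMS, could cover only part of the loss. Rpl29 went from 71.9 and 66.2 CPM in KM to 0.827 and 0.728 CPM in KMS. How many reads were assigned to none of the copies stays open. The copy Gm6344 went from 342 and 234 counts in KM to 0 and 0 in KMS, and the sum over Rpl29 and its copies fell from 148 to 90.4 CPM, a log2 change of -0.71, within the range of other ribosomal protein genes (Rps21 at -1.81). Alleles of another strain carried along with the floxed Setd2 gene cannot be told apart from this, since Rpl29 lies 4.15 Mb from Setd2 but a carried segment need not alter its other genes. Of genes within 10 Mb of Setd2, 4.97% had an absolute log2 fold change above 2, against 4.88% elsewhere on the chromosome.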

How the results depend on the processing

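Robust estimation, the removal of RNAs without poly(A) tails and DESeq2 with the block were chosen after the data were seen. Against 5 calls (20% higher in KMS), edgeR with library totals alone gave 3 calls (33.3% higher, median of all genes shifted to -0.13). limma-voom gave 1, a mean of at least 1 CPM 3, robust estimation 233 (89 higher and 144 lower), and the removal of RNAs without poly(A) tails, mitochondrial genes and Malat1 2. DESeq2 gave 1767 calls (873 higher and 894 lower) and an adjusted p under 0.10 in edgeR 1216 (529 and 687), and the cause of these differences was not tested. With each library left out in turn, which leaves a lone library assumed to vary like the other group, the count ranged from 0 (without KMS replicate 1 or 2, 3437 and 2455 genes at an unadjusted p under 0.05 in edgeR) to 1786 (without KM replicate 1). The replicate block gave 815 calls (290 and 525) in edgeR and 888 (429 and 459) in DESeq2, and all 5 calls were among each. Deviations of libraries with equal numbers correlated at 0.117, and at 0.0646 without sex-linked genes, so the numbers were not taken to pair the libraries. The block is the same model as a term for sex. DESeq2 size factors gave 7 calls (28.6% higher), upper-quartile factors 5, no filter 6, and the removal of mitochondrial, haemoglobin and sex-linked genes 6. Setd2 and Myc passed in none of these settings. Of 25 lists, 15 were called, 14 to 17 in the other settings with the preset correlation, 0 with an estimated correlation (lowest adjusted p = 0.581, limma) and 0 with fry (lowest adjusted p = 0.304). The calls of proximal tubule, loop of Henle, oxidative phosphorylation, fatty acid oxidation, injury, leukocytes, cell cycle, matrix, TGF-beta, Myc targets and epithelial identity held in each of 14 other settings. Hypoxia and interferon were lost in 4 of them each, p53 and podocytes in 1 each, and Wnt/beta-catenin targets were called in 7. Cilia and cystic disease, collecting duct and immediate early genes gained a call in 2 settings each. Mitochondrial transcripts and sex-linked genes gained it in 1 each. Endothelium and erythrocytes were called in 1 setting in each direction. With a library left out, the erythrocyte median ranged from -2.27 to 1.66 (without KM replicate 1, limma adjusted p = 3.7e-05). The endothelial median ranged from -0.40 without KMS replicate 1 to 0.19 without KMS replicate 2, so its direction depended on the library left out. The cause of these turns was not tested. The pseudocount alternative does not apply to counts and was not run.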

Other observations

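The lists described here were chosen after the data were seen, and their genes partly for their values, so their counts are not independent evidence. Genes of peroxisomes and glutathione metabolism were positive in 20 of 20 cases with a median log2 fold change of 0.79 in KMS, and 10 rose when adjusted over the list alone (limma camera adjusted p = 5.8e-10 over 4 added lists, estimated-correlation p = 0.079). With the term for sex, the glutathione transferase gene Gstt1 rose from 52.5 and 45.7 CPM in KM to 168.9 and 171.8 CPM in KMS, and Dpep1, a brush border dipeptidase, from 72.9 and 62.5 to 232.7 and 269.2 CPM (edgeR adjusted p = 0.010 and 0.011). Genes of cytoplasmic ribosomal proteins went the other way, with 69 of 77 negative and a median of -0.45 (limma camera adjusted p = 6.1e-10, estimated-correlation p = 0.244), and 20 fell when adjusted over the list alone. Translation factors and poly(A)-binding proteins had a median of -0.34 (limma camera adjusted p = 1.2e-04, estimated-correlation p = 0.054), with Pabpc1 at 602 and 802 CPM in KM and 181 and 185 CPM in KMS. The directions of these medians were the same with TMM, DESeq2 size factors, upper-quartile factors and library totals.

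Genes of urothelium and basal keratins were lower in KMS for 10 of 10 tested members (median -5.82, limma camera adjusted p = 1.4e-09, estimated-correlation p = 0.124), with summed CPM of 20.6 in KM replicate 1, 163 in KM replicate 2, and 1.76 and 2.79 in KMS, so the largest part lay in 1 library. Kap and Slc7a13, members of the proximal tubule list chosen after their values were seen, are known to be higher in male mouse kidney. Both counted as positive in that list (log2 fold change 2.70 and 4.64), but both were lower in KMS in the female pair. Kap had 1480 CPM in KM replicate 1 (female), 827 in KM replicate 2 (male), 56.6 in KMS replicate 1 (female) and 14930 in KMS replicate 2 (male), and Slc7a13 had 1.13, 14.5, 0.413 and 387 CPM in the same order. The authors' deposited table also ranks genes by a ratio of mean raw counts. Its median over all genes was 0.486, against 0.965 for the authors' ratio of normalised means. A raw ratio above 1.5 was reached by 299 genes and a normalised ratio above 1.5 by 2984, of which 1813 had a raw ratio under 1.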
